A study of Mus musculus with 6 samples.

How the data were processed

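Gene expression was measured in ovaries of C57BL/6 female mice on Illumina Mouse Ref-8 v2 BeadChips, arrays that read each transcript through many beads carrying the same probe. Total RNA from adult ovaries was turned into biotin-labelled cRNA and hybridised, per the labels' protocols. There were 6 arrays, 3 of room-air controls and 3 of mice that inhaled cigarette smoke, and the group of each array was taken from the labels. The labels do not say whether an array held the RNA of 1 animal or of several, so the p-values measure only the spread between these samples, which may be partly technical. The stage of the oestrous cycle and the way the ovaries were dissected were not given in the sources used here.

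The deposited table of non-normalized values holds an intensity for each of 25697 probes on each array with no sign in the values of a background subtraction. A second deposited table holds the authors' processed values on a log2 scale. All 6 of its columns share the same distribution, and its values meet log2 of the intensity at high signals and are compressed at low ones. The package lumi is named for the processing, per the submitters' processing notes, and its version, the transformation and the normalization were not given in the sources used here. The authors' deposited table of the comparison gives a p-value for each probe, a step-up adjusted p-value and a smoke-over-control ratio. That ratio equals 2 to the power of the difference of the group means of the processed values, within a relative gap of 5.03e-06. The authors also give a signed fold, treated here as a score, which is the ratio where it is above 1 and minus its inverse otherwise, and an enrichment score for Gene Ontology terms, which is minus the natural log of its p-value. The p-values of 41 probes were stored as clock times in the authors' table and were read as seconds divided by 86400, and 103 of its lines were empty as used here. The comparison was a 2-group analysis of variance per probe as the sheet and column names have it, and its software and filters were not given in the sources used here. A plain analysis of variance run here on the authors' processed values gave p-values within 1 percent of theirs for 99.996% of the probes.

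From the non-normalized intensities, the background of each array was corrected with the normexp model of limma 3.58.1 in R 4.3.3 with an offset of 50, followed by log2 and quantile normalization. The analysis fixed before the data were examined had planned normexp with a background taken from detection p-values, and a filter on those p-values. Columns for detection p-values were blank in the table as used here and it held no negative control probes, so neither step could be run. The alternative listed beforehand, normexp with an offset of 50 and quantile normalization, took the place of the first. In place of the second, the background of an array was taken as the mode of its signals, and its spread from the signals below the mode. A probe counted as above background where its signal exceeded the mode by 1.64 of these standard deviations, the one-sided 5% point of a normal distribution. Probes above background on at least 3 of the 6 arrays were kept, which left 15251 named probes, and each gene was represented by its probe of highest mean log2 signal over the 6 arrays, which left 11371 genes. Where several probes measured a gene, 2812 genes in all, 2 genes had a second probe past the threshold in the opposite direction. They were Snapc3, with log2 changes of 0.29 and -0.32, and Cstf3, with -0.35 and 0.30.

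Probes were named by the authors' annotation, and the symbols were brought up to date through the gene identifier with a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. A current symbol was found this way for 23692 probes, and 3921 symbols changed. Chromosomes are those of the authors' annotation, whose genome build was not given in the sources used here. The 103 probes without annotation, of which 56 were above background on at least 3 arrays, were left out.

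Smoke was compared with room air, gene by gene and two-sided, with limma's lmFit and eBayes with a trend in the variance prior, and p-values were adjusted by the Benjamini-Hochberg method. A gene passed at an adjusted p under 0.05. The prior carried 17.1 degrees of freedom beside 4 residual ones, and the median standard error of a log2 change was 0.10. A change of log2 signal is compressed for genes near background, because of the offset. Where a gene was below background on all arrays of a group, its fold is given as a lower bound. The bound sets the mean of the brighter group against the mean of, for each array of the dimmer group, the lowest signal among probes above background or the gene's own signal, whichever was higher, all as normalized log2 values. With such genes at their bound, the medians of the proliferation, inflammation and oviduct lists were the same to the decimals printed, and other medians that moved are given beside the list.

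A set of 37 gene lists, covering cell types of the ovary and of neighbouring tissue, steroid synthesis, response to smoke constituents, immunity and stress, was fixed at the same time. The lists named 1197 genes, of which 1102 were found among the 18068 symbols on the array, and each list had at least 5 genes tested. Each was tested with camera against all other genes at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all with Benjamini-Hochberg adjustment over the lists. The estimated version also rests on the 4 residual degrees of freedom. Fry asks whether the genes of a list move on balance one way and does not compare the list with other genes. Of the 17 lists past the threshold, 5 also passed with an estimated correlation (surface epithelium, proliferation, granulosa, adipocyte and interferon), and fry called 25 of the 37.

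Genes were named by a rule fixed beforehand. It took the 14 genes with the largest rise and the 14 with the largest fall among those past the threshold whose groups did not overlap, up to 4 members of lowest p of each list past the threshold and of the aryl hydrocarbon receptor, NRF2, steroidogenesis and oocyte lists, and up to 6 genes per direction of the authors' list of changed genes. Probes with no gene symbol or a clone name were passed over, 0 among the rises and 3 among the falls. Further list members, above all those that moved against their list and those of lists that did not pass, were chosen after their values were seen. Some list members are not reported here by name.

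The gene and list steps were tested on simulated arrays made from these 6. Of the 200 changed genes drawn, 40 to 44 per fold were among the 10622 genes tested. Of these, 20.4% were recovered at 1.25-fold, 70.0% at 1.5-fold, 86.4% at 2-fold and 93.2% at 3-fold. Their median measured folds were 1.18, 1.43, 1.79 and 2.49. In that simulation 5 unchanged genes were called, 4.13% of the calls. With no change simulated, 0 genes and 0 lists were called. Simulated probes varied independently of each other, so this run cannot show how often lists of correlated genes are called falsely. The alternatives covered background correction, the scaling between arrays, the authors' processed values, the background filter, the choice of probes, a block for the replicate number, array weights, the variance prior, the threshold and test, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 and tables handled with pandas 2.3.3. The number of arrays limits the precision of every value.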

Results

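Ovarian gene expression was compared between adult female mice that breathed cigarette smoke through the nose and mice kept in room air, to ask which genes of the ovary respond to long exposure. Smoke came from 12 reference cigarettes per session, with 60 minutes per session, 2 sessions per day, 5 times per week, for 12 to 18 weeks, per the labels. Particulate matter was given as 2.7 mg, and 21 mice were exposed together. There were 3 room-air and 3 smoke arrays of 25697 probes. Median raw signals ran from 153.4 to 191.1, and 14983 to 15311 probes per array, 58.3% to 59.6%, lay above background. Arrays of the same group correlated at 0.9951 to 0.9964 over genes and arrays of different groups at 0.9882 to 0.9901, and the first principal component, with 59.3% of the variance, placed all smoke arrays on one side and all room-air arrays on the other. The second component carried 12.9%.

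Of 37 fixed gene lists 17 were shifted in smoke, 8 upward and 9 downward. The surface epithelium, proliferation, granulosa and adipocyte lists went upward and the interferon list downward, and these 5 calls held with an estimated correlation, at adjusted p values of 0.0186 to 0.0218. The other 12 calls, among them the downward ones of the inflammation, macrophage, lymphocyte, luteal, theca and matrix lists, were lost with it, at adjusted p values of 0.0792 to 0.155. Ovgp1, the oviductal glycoprotein, showed the largest rise, 27.6-fold, followed by the adipocyte product Cfd at 8.01-fold and the cytochrome P450 gene Cyp2e1 with a log2 change of 2.81. The largest falls were those of the proton pump Atp12a at 5.57-fold, Tlcd4 at 3.96-fold and the interferon-induced chemokine Cxcl9 at 3.71-fold. These sizes depend on the scale. On the authors' processed values, which are compressed at low signals, the log2 changes were smaller by over 1.5 times for 36 of 92 named genes, with Atp12a at -1.05, Tlcd4 at -1.23, Cxcl9 at -0.86 and Cyp2e1 at 1.58, and Abcb1b had the largest fall among them at -1.63. The genes changed in smoke against room air numbered 2053 of 11371 tested, or 18.1%, with 1008 higher and 1045 lower in smoke. With median scaling in place of quantile normalization the split was 1080 higher and 659 lower, so that the share of higher calls moved from 49.1% to 62.1%. Most changes were small: the median size of a called log2 change was 0.38, and 153 called genes were at least 1.5-fold higher and 188 at least 1.5-fold lower. At least 2-fold changes numbered 39 higher and 27 lower. The 3 smoke values did not overlap the 3 room-air values in 2009 of the called genes and in 33.5% of all genes tested, against 10% by chance. Before adjustment, 3451 genes had a p under 0.05.

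**Figure D1:**
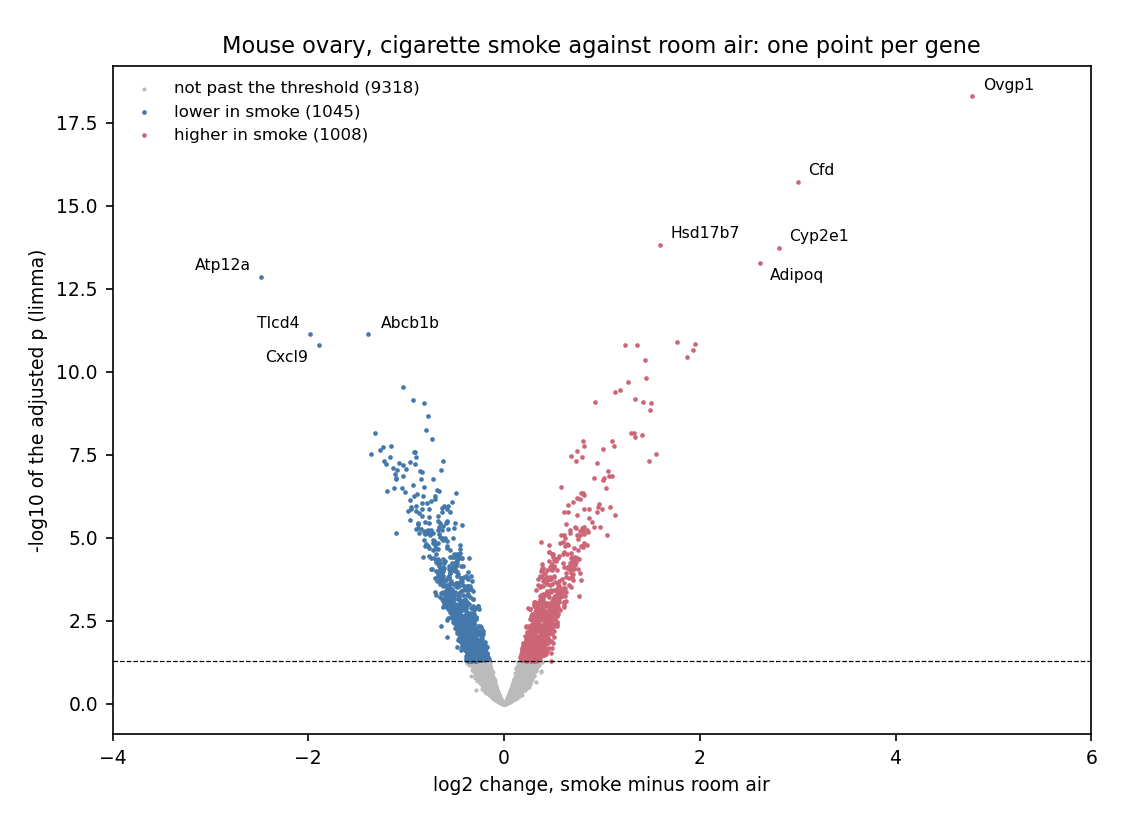
Log2 change of smoke minus room air (x axis) against the negative log10 of the adjusted p from limma (y axis) for 11371 genes, one point per gene. Red points are the 1008 genes higher in smoke and blue points the 1045 lower, and Ovgp1, with a log2 change of 4.78, stands apart from the rest.

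The strongest rises were those of Ovgp1, Cfd, Cyp2e1 and Adipoq. Ovgp1 on chromosome 3 went from a mean log2 signal of 6.70 ± 0.14 (SD, n = 3) in room air to 11.49 ± 0.03 (SD, n = 3) in smoke, a log2 change of 4.78 ± 0.10 SE with a limma adjusted p of 4.99e-19. Its second probe rose by 0.54 ± 0.11 SE, with an adjusted p of 0.00175. The serine protease gene Cfd on chromosome 10, abundant in fat, rose from 8.55 to 11.55, a log2 change of 3.00 ± 0.09 SE. Cyp2e1 on chromosome 7, an enzyme that oxidises ethanol and nitrosamines, rose from 7.09 to 9.89, and Adipoq on chromosome 16, the gene of the fat hormone adiponectin, from 6.74 to 9.36, or 6.12-fold. The epithelial secreted proteins encoded by Wfdc2 and Ltf rose 3.86-fold and 3.82-fold. Fxyd4, a regulator of the sodium pump, was below background on all room-air arrays and at least 2.60-fold higher in smoke, with an adjusted p of 3.44e-11. The adhesion molecule gene Nrcam rose 3.40-fold. Hsd17b7, which encodes a luteal enzyme of oestradiol and cholesterol synthesis, rose 3.02-fold from an already high signal of 11.98 to 13.57. Car3 rose 2.94-fold, with 2 of 3 room-air arrays above background, Slc5a4b 2.82-fold, Dner 2.82-fold, Ihh, the gene of the Indian hedgehog ligand, 2.79-fold, and the carboxylesterase gene Ces1d 2.73-fold. Adipocyte and oviduct markers as lists had medians of 0.38 and 0.34.

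The strongest falls were those of Atp12a, Tlcd4, Cxcl9 and Abcb1b. Atp12a on chromosome 14 went from 9.03 to 6.55, a log2 change of -2.48 ± 0.10 SE with an adjusted p of 1.34e-13, and 2 of 3 smoke arrays were above background. Tlcd4 on chromosome 3 changed by -1.98 ± 0.10 SE. Cxcl9 on chromosome 5 went from 8.94 to 7.05, and Abcb1b on chromosome 5, which encodes a drug efflux pump, was 2.62-fold lower, from 12.52 to 11.13. The monocyte chemokine gene Ccl7 was 2.56-fold lower, the T cell receptor chain gene Cd3g 2.35-fold lower and the monocyte chemokine receptor gene Cx3cr1 2.35-fold lower. Adh7, the gene of an alcohol and retinol dehydrogenase, was 2.25-fold lower and Cyp4f14, another cytochrome P450 gene, 2.16-fold lower. Ngef was 2.40-fold, Bpifb6 2.31-fold, Serpina3c 2.23-fold, Klhl30 2.18-fold and Sez6l2 2.16-fold lower.

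**Figure D2:**
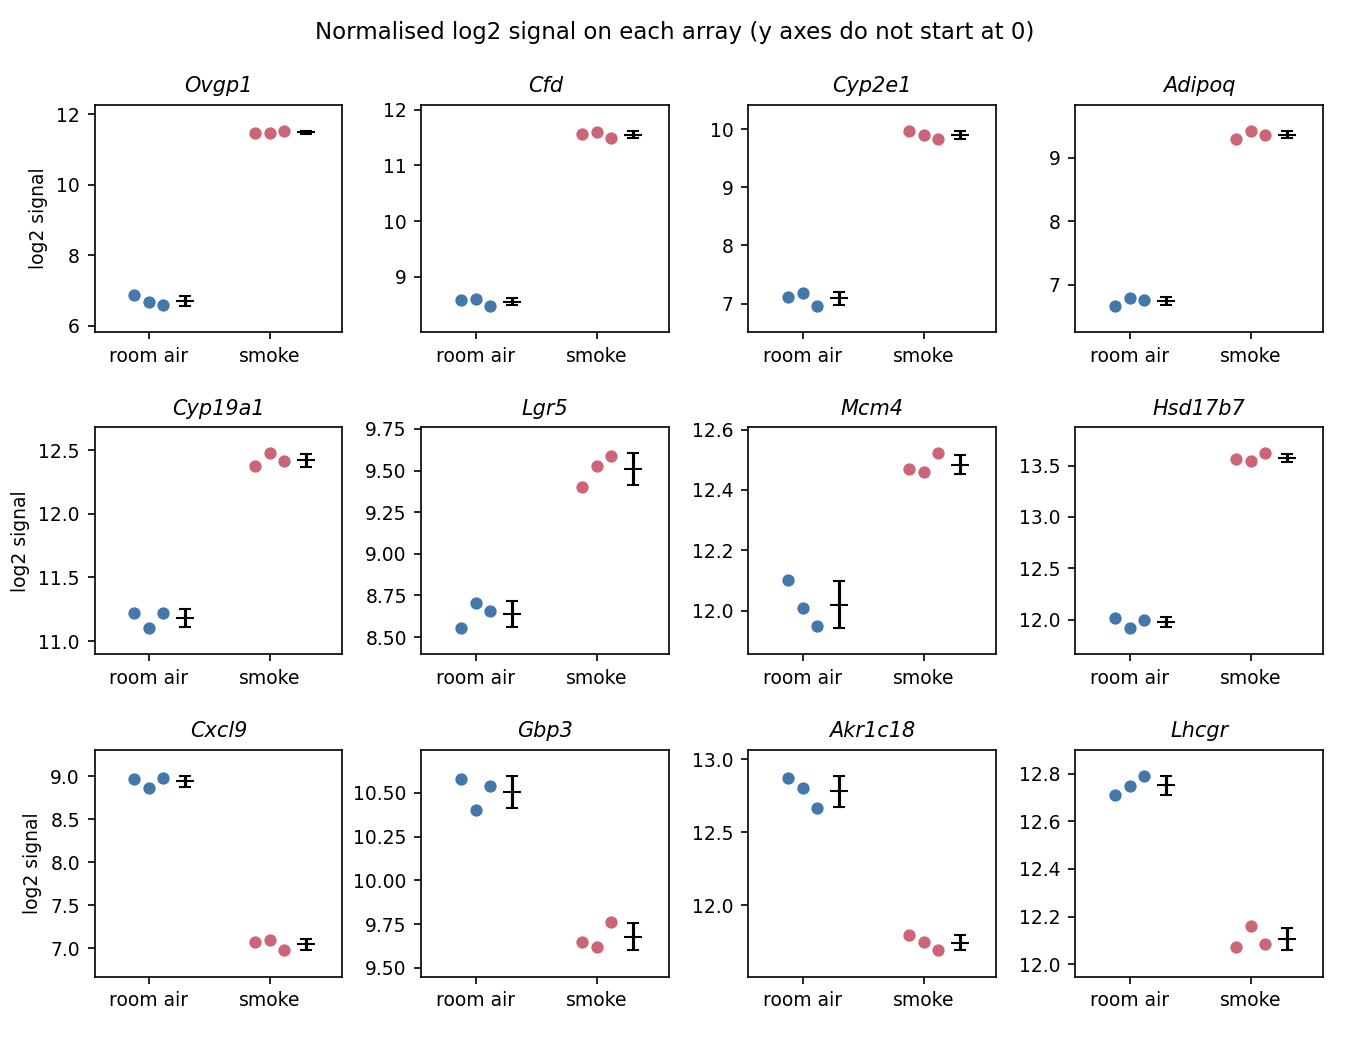
Normalized log2 signal (y axis, not starting at 0) of 12 named genes on each of the 3 room-air (blue) and 3 smoke (red) arrays, with black bars for the mean and caps for ± SD of the 3 arrays. No array of one group reached the range of the other for these genes, a condition that the naming rule set for the largest rises and falls. Ovgp1 lay at 6.70 in room air and 11.49 in smoke, and Cxcl9 at 8.94 and 7.05.

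The surface epithelium, granulosa and proliferation lists were shifted upward. Of 15 surface epithelium markers, 13 rose, 0 fell and 2 did not pass, with 13 also past the threshold adjusted over the list alone, a median log2 change of 0.71 and a camera adjusted p of 2.12e-12 (adjusted p = 0.0186 with an estimated correlation). Lgr5, a marker of epithelial stem cells, rose by 0.87 ± 0.10 SE, Cldn15 by 0.82, the keratin gene Krt7 by 0.80 and the uroplakin gene Upk3b by 0.71. Aldh1a2 at 0.09 and Muc1 at 0.07 did not pass. Among 21 granulosa markers 11 rose and 0 fell, 12 and 0 adjusted over the list alone, with a median of 0.36 and a camera adjusted p of 2.75e-08 (adjusted p = 0.0218 with an estimated correlation). The granulosa median was 0.20 without smoke array 3, 0.24 on the authors' processed values, 0.14 with all probes tested and 0.12 without a background filter. The aromatase gene Cyp19a1 rose by 1.24 ± 0.07 SE, Nap1l5 by 1.19, the follistatin gene Fst by 0.93 and the nuclear receptor gene Nr5a2 by 0.62. Proliferation genes numbered 24 higher and 0 lower of 38, 27 and 0 adjusted over the list alone, with a median of 0.30 and a camera adjusted p of 3.51e-11 (adjusted p = 0.0186 with an estimated correlation). The cyclin gene Ccnd2, active in granulosa cells, rose by 0.81 ± 0.07 SE, and the replication genes Mcm4, Mcm5 and Uhrf1 by 0.46, 0.44 and 0.37. Beside these lists, oviduct markers had a median of 0.34, with 4 of 10 not past the threshold (adjusted p = 0.148 with an estimated correlation).

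Oocyte genes were shifted upward by little. Of 37 tested, 6 rose, 0 fell and 31 did not pass, with 5 and 0 adjusted over the list alone, a median of 0.18 and a camera adjusted p of 0.000130 (adjusted p = 0.148 with an estimated correlation). The median was 0.11 on the authors' processed values. Oosp1 rose by 0.31 ± 0.07 SE, Ftdc2 by 0.31 and Nlrp14 by 0.28. Ooep, of the maternal complex under the oocyte membrane, rose by 0.20 with an adjusted p of 0.0218, and lost its call under 6 of 16 alternatives, over which its adjusted p ran from 0.0129 to 0.120. These were Ooep without room-air array 2 (0.103), room-air array 3 (0.0598), smoke array 2 (0.112) or smoke array 3 (0.0542), median scaling (0.0944) and no trend in the variance prior (0.120). Follicle activation genes split into 3 higher, 2 lower and 22 not past the threshold, 3 and 2 adjusted over the list alone, with a camera adjusted p of 0.440. Amh and Foxl2, made by granulosa cells, rose by 0.36 and 0.48 and Mtor by 0.38, while Pik3r1 changed by -0.80 and Bmp4 by -0.63. Foxl2 passed narrowly (limma adjusted p = 0.0499), its groups overlapped, and its 3 smoke values were 7.80, 8.31 and 8.83. Amh was highest on smoke array 3, at 11.41, against 10.89 and 10.95 on smoke arrays 1 and 2. Of 18 ovulation and cumulus genes 2 rose and 2 fell, 2 and 5 adjusted over the list alone (camera adjusted p = 0.371), with Lhcgr at -0.65, Star at -0.51, Errfi1 at 0.45 and Runx1 at 0.30. WNT and BMP signalling genes went both ways, 4 higher and 6 lower of 34, 5 and 9 adjusted over the list alone (camera adjusted p = 0.804), with a median of 0.01, a mean of -0.01 and a test pointing down, among them Inhba, an activin subunit gene, at 0.38 and Wnt5a at -0.39.

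The luteal and theca lists were shifted downward. The stage of the oestrous cycle was not given in the sources used here. A difference of stage between the groups was therefore not tested for these lists or for the granulosa list. Of 21 luteal genes 8 fell and 2 rose, the same counts adjusted over the list alone, with a median of -0.15 and a camera adjusted p of 0.00126 (adjusted p = 0.0901 with an estimated correlation). Akr1c18, whose product inactivates progesterone, changed by -1.04 ± 0.07 SE, the lipoprotein receptor gene Scarb1 by -0.77, the luteinizing hormone receptor gene Lhcgr by -0.65 and the cholesterol carrier gene Star by -0.51. Hsd17b7, at 3.02-fold, and Hsd3b1, an enzyme gene of progesterone synthesis, at 0.27 ± 0.08 SE, rose against their list. Theca markers showed 5 lower, 1 higher and 6 not past the threshold of 12, with 5 and 1 adjusted over the list alone and a camera adjusted p of 0.0175 (adjusted p = 0.148 with an estimated correlation, and 0.0501 for the list without a trend in the variance prior, in a range of 0.000326 to 0.148 over 18 alternatives). Their median was -0.01 and their mean -0.19. That median was 0.01 without smoke array 2 and between -0.03 and -0.14 under 7 other alternatives. Bmp4 changed by -0.63, Insl3, the gene of a theca hormone, by -0.61, and Fabp3 by -0.57, and the member that rose was again Hsd3b1. Lhcgr, which the luteal list also holds, was another of the 5 that fell. Cyp17a1 at -0.04 was among the 6 that did not pass.

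Steroid synthesis as a whole had 4 genes higher and 9 lower of 29, 4 and 10 adjusted over the list alone, and did not pass (camera adjusted p = 0.103). It passed with all probes tested (0.00449), with fry (0.0413) and without smoke array 3 (0.0489), in a range of 0.00449 to 0.276 over 18 alternatives, and its median of -0.06 ran from -0.02 without smoke array 2 to -0.12 with all probes. Hsd17b7, Cyp19a1, Nr5a2 and Hsd3b1 rose, while Akr1c18 at -1.04, Lhcgr at -0.65 and Srd5a1, a steroid reductase gene, at -0.81 were among those that fell. The cholesterol synthesis list had 3 higher and 4 lower of 21, 3 and 5 adjusted over the list alone (camera adjusted p = 0.967). Hsd17b7, Mvd at 0.55 and Sqle at 0.32 rose, while Sc5d changed by -0.42, Nsdhl by -0.34 and Fdps by -0.17. Its median was -0.07 and its mean 0.03, camera pointed down and fry up.

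The interferon and inflammation lists were shifted downward. Of 26 interferon-stimulated genes 16 fell and 0 rose, 18 and 0 adjusted over the list alone, with a median of -0.35 and a camera adjusted p of 7.22e-10 (adjusted p = 0.0186 with an estimated correlation). The interferon median was -0.19 on the authors' processed values. The guanylate-binding protein gene Gbp3 changed by -0.83 ± 0.09 SE, Usp18 by -0.80, the ubiquitin-like modifier gene Isg15 by -0.78 and the GTPase gene Igtp by -0.72. Among 34 inflammatory cytokine and chemokine genes 15 fell and 5 rose, 18 and 9 adjusted over the list alone, with a median of -0.22 and a camera adjusted p of 0.00158 (adjusted p = 0.155 with an estimated correlation). The inflammation median was -0.07 on the authors' processed values and -0.08 without a background filter. Cxcl9, Ccl7 and the neutrophil chemokine gene Cxcl1, at -1.10, fell, whereas Cxcl12, the gene of a chemokine that retains leukocytes in tissue, rose by 0.79 ± 0.07 SE, Lcn2 by 0.42, Ccl9 by 0.39 and Ccl6 by 0.38. Saa2 was below background on all room-air arrays and at least 1.20-fold higher in smoke.

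The macrophage and lymphocyte lists were shifted downward as well. Macrophage markers had 9 lower and 1 higher of 25, 10 and 1 adjusted over the list alone, with a median of -0.15 and a camera adjusted p of 0.0142 (adjusted p = 0.148 with an estimated correlation, and 0.0596 with all probes tested, in a range of 0.00407 to 0.148 over 18 alternatives). The macrophage median was -0.04 on the authors' processed values and without a background filter, -0.09 with all probes tested and -0.10 with median scaling. Cx3cr1, at -1.23, led this list, followed by Aif1 at -0.62 and the mannose receptor gene Mrc1 at -0.55, while Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 0.81 ± 0.07 SE. Of 14 lymphocyte markers 6 fell and 2 rose, 7 and 2 adjusted over the list alone, with a median of -0.23, or -0.20 with a gene below background in one group set to its bound, and a camera adjusted p of 0.00648 (adjusted p = 0.148 with an estimated correlation). The lymphocyte median was -0.07 on the authors' processed values and -0.14 without a background filter. Cd3g changed by -1.24, Cd52 by -0.74 and Cd3d by -0.60, but the cytotoxic granule gene Prf1 rose by 0.96 ± 0.11 SE and Cd8b1 by 0.38. Granulocyte and mast cell markers did not pass, with 1 higher and 3 lower of 9, the same adjusted over the list alone (camera adjusted p = 0.465). S100a9 at -0.53, Ear2 at -0.49 and S100a8 at -0.38 fell and Ltf rose, so that the median was -0.10 and the mean 0.03, with camera pointing down and fry up.

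The endothelial and matrix lists were shifted downward. Of 21 endothelial markers 5 fell and 0 rose, 8 and 0 adjusted over the list alone, with a median of -0.17 and a camera adjusted p of 0.00126 (adjusted p = 0.148 with an estimated correlation). The endothelial median was -0.11 with median scaling. The tight junction gene Cldn5 changed by -0.56 ± 0.09 SE, Egfl7 by -0.48, the angiopoietin receptor gene Tek by -0.43 and Robo4 by -0.42. Of 41 matrix and fibroblast genes 13 fell and 3 rose, 14 and 3 adjusted over the list alone, with a median of -0.09 and a camera adjusted p of 0.00126 (adjusted p = 0.0792 with an estimated correlation). The matrix median was -0.15 without room-air array 1. Tnc, the tenascin gene, changed by -0.96 ± 0.09 SE, the growth factor gene Ccn2 by -0.78 and Lum by -0.49, while Fbln2, Fbln1 and Col6a2 rose by 0.40, 0.39 and 0.27. Smooth muscle and pericyte markers did not pass, with 4 lower and 0 higher of 18, 4 and 1 adjusted over the list alone (camera adjusted p = 0.318), namely Kcnj8 at -0.35, Tpm2 at -0.25, Actg2 at -0.23 and Mylk at -0.20.

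Among the genes tested, those that respond to smoke constituents in other tissues were not higher as groups. Aryl hydrocarbon receptor targets, which respond to polycyclic hydrocarbons, had 0 higher, 2 lower and 7 not past the threshold of 9. Adjusted over the list alone the counts were 0 and 3. Cyp1a1 and Cyp1a2, which the list also names, were not among the 9 genes tested, so the size of any change of theirs is not given. The filter kept every named probe above background on at least 3 arrays. Any probe of these genes was therefore not above background on all 3 smoke arrays. Whether the array holds such probes is not stated here. Ugt1a6a changed by -0.65 ± 0.11 SE and Aldh3a1 by -0.45 ± 0.11 SE, while Nqo1 at -0.30 (adjusted p = 0.0633), Tiparp at -0.26 (adjusted p = 0.136), the receptor's repressor gene Ahrr at -0.07 and Cyp1b1 at 0.05 did not pass. The list had a median of -0.22 and a camera adjusted p of 0.0452 (adjusted p = 0.155 with an estimated correlation), and its call was lost under 7 of 18 alternatives, over which the adjusted p ran from 0.00213 to 0.155. It was lost without a background filter (0.0694), with the stricter filter (0.0652) and with array weights (0.0530). The median was -0.14 without smoke array 3 and -0.07 on the authors' processed values and without a background filter. Without 1 array it was lost for room-air array 1 (0.0908), room-air array 2 (0.0596) and smoke array 1 (0.0728). Aldh3a1 lost its call without room-air array 1 (adjusted p = 0.0504) or without smoke array 3 (adjusted p = 0.0521), in a range from 0.00695 over 16 alternatives. Nqo1 passed without smoke array 2 (adjusted p = 0.0425) and without a trend in the variance prior (adjusted p = 0.0473), with a highest value of 0.191.

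NRF2 targets and antioxidant enzymes had 1 higher and 7 lower of 32, 2 and 8 adjusted over the list alone, and did not pass (camera adjusted p = 0.103), with a median of -0.01. The list passed without a background filter (0.0437), with all probes tested (0.0451) and with fry (0.0120), in a range up to 0.254. Its median ran from -0.000134 without room-air array 3 to -0.0318 with all probes tested. The epoxide hydrolase gene Ephx1 changed by -0.73 ± 0.06 SE, the extracellular superoxide dismutase gene Sod3 by -0.57, Me1 by -0.45 and Taldo1 by -0.39, while the haem oxygenase gene Hmox1 rose by 0.34 ± 0.11 SE. Of 43 xenobiotic-metabolising enzymes 3 rose and 12 fell, 3 and 16 adjusted over the list alone (camera adjusted p = 0.0516). Those that rose were Cyp2e1, Ces1d and Cyp2f2, the last by 1.04 with 1 of 3 room-air arrays above background. Among those that fell were the glutathione transferase gene Gsta2 at -0.95 and the alcohol dehydrogenase gene Adh1 at -0.93.

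Among markers of tissue next to the ovary, the adipocyte and oviduct lists were shifted upward. Of 16 adipocyte markers 10 rose and 1 fell, 10 and 2 adjusted over the list alone, with a median of 0.38, or 0.25 with genes below background in one group set to their bound, and a camera adjusted p of 2.64e-10 (adjusted p = 0.0186 with an estimated correlation). The adipocyte median was 0.19 without a background filter and 0.22 with the stricter filter. Beside Cfd and Adipoq, the desaturase gene Scd1 rose by 1.36 ± 0.07 SE and Cidec, which coats lipid droplets, was at least 2.01-fold higher, but Plin1, the gene of another lipid droplet coat protein, changed by -0.47 ± 0.12 SE. In room air, 12 of these 16 genes were above background on all 3 arrays. Oviduct epithelium markers had 5 higher, 1 lower and 4 not past the threshold of 10, 7 and 1 adjusted over the list alone, with a median of 0.34 and a camera adjusted p of 4.30e-05 (adjusted p = 0.148 with an estimated correlation). The oviduct median was 0.13 on the authors' processed values and 0.15 without a background filter. Ovgp1 and Wfdc2 rose most, Krt7, which the surface epithelium list also holds, rose by 0.80, the axoneme gene Tekt1 by 0.37, and Dynlrb2, below background on all room-air arrays, was higher by at least 0.58 on the log2 scale. Tppp3 changed by -0.54 ± 0.10 SE, and Foxj1, the regulator of ciliated cells, had a change of 0.00. In room air, 9 of these 10 genes were above background on all 3 arrays. Skeletal muscle markers had 0 of 10 past the threshold either way, 0 and 0 adjusted over the list alone (camera adjusted p = 0.473, median 0.10, or 0.09 with bounds). Erythrocyte markers had 1 higher and 2 lower of 8, the same adjusted over the list alone (camera adjusted p = 0.440), with the globin genes Hbb-b1 at -0.54 and Hba-a1 at -0.37.

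The heat shock and clock lists were shifted upward. Of 21 heat shock genes 8 rose and 1 fell, the same adjusted over the list alone, with a median of 0.14 and a camera adjusted p of 0.00315 (adjusted p = 0.148 with an estimated correlation). The heat shock median was 0.06 on the authors' processed values. The chaperone genes Hsp105 and Dnajb1 rose by 0.78 ± 0.08 SE and 0.61 ± 0.07 SE, and the co-chaperone genes Ahsa1 and Chordc1 by 0.37 and 0.36, while Hspb1, a small heat shock protein gene, changed by -0.34. Of 14 clock genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 0.23 and a camera adjusted p of 0.00620 (adjusted p = 0.152 with an estimated correlation). The clock median was 0.14 on the authors' processed values. The repressor arm genes Per2, Ciart and Per1 rose by 0.74, 0.70 and 0.41, and the activator gene Arntl changed by -0.42 ± 0.11 SE. The activator gene Clock rose, by 0.24 (limma adjusted p = 0.0383), and the repressor gene Nr1d1, at -0.11, did not pass. The hour of tissue collection was not among the sample details used here, so a difference in it between the groups was not tested.

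No other stress, death or metabolic list passed. Unfolded protein response genes had 5 higher and 2 lower of 22, 7 and 3 adjusted over the list alone (camera adjusted p = 0.103), with the chaperone genes Hspa5 at 0.63 and Calr at 0.54, and Ddit3 at -0.34 and Sel1l at -0.25. Hypoxia genes had 4 higher and 1 lower of 28, 5 and 2 adjusted over the list alone (camera adjusted p = 0.103), with Ak4 at 0.70, Egln3 at 0.57 and P4ha2 at -0.37. Immediate early genes had 1 higher and 4 lower of 19, 3 and 4 adjusted over the list alone (camera adjusted p = 0.0647), with Ier3 at -0.91 and Fosb at 0.33. Glucocorticoid-responsive genes had 5 higher and 5 lower of 20, 6 and 5 adjusted over the list alone (camera adjusted p = 0.554), among them Ddit4 at 0.47 and Gadd45b at -0.57. Apoptosis genes had 4 higher and 2 lower of 33, the same adjusted over the list alone (camera adjusted p = 0.461), with the pro-apoptotic genes Bcl2l11 at 0.41, Bik at -0.88 and Bmf at -0.33. Targets of p53 and DNA repair genes had 5 higher and 3 lower of 43, the same adjusted over the list alone (camera adjusted p = 0.371). The checkpoint kinase genes Chek1 and Atm rose by 0.52 and 0.41, whereas the p53 targets Cdkn1a and Gadd45a changed by -0.46 and -0.27. Fatty acid oxidation had 6 lower and 0 higher of 25, the same adjusted over the list alone (camera adjusted p = 0.103), with Decr1 at -0.35. Of 58 oxidative phosphorylation genes 1 rose, Ndufa10 at 0.19, and 1 fell, Ndufa3 at -0.16, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.169). Of 50 ribosomal protein genes 0 rose and 1 fell, Rps25 at -0.23, and 0 and 0 adjusted over the list alone (camera adjusted p = 0.832). Their median of 0.01 turned to -0.01 with median scaling, their mean was -0.0003 and the test pointed up.

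**Figure D3:**
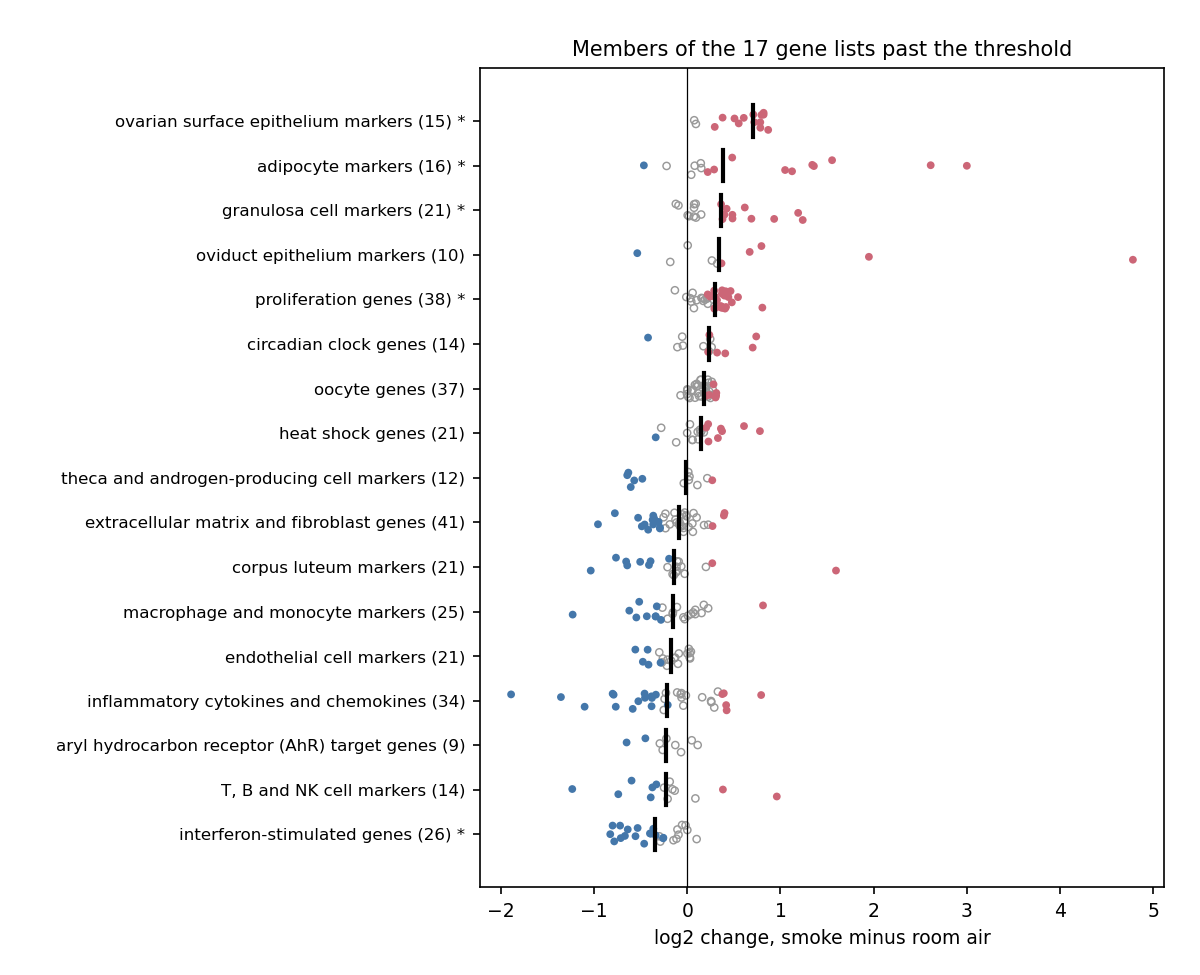
Log2 change of smoke minus room air (x axis) for the genes of the 17 lists past the camera threshold, one point per gene, with the number tested in brackets and a black bar for the median. Filled points passed the gene test (red higher, blue lower), open points did not, and asterisks mark the 5 lists also past the threshold with an estimated correlation; medians ran from 0.71 for surface epithelium to -0.35 for interferon-stimulated genes.

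The authors' deposited table of changed genes was set beside these results. It lists 191 probes of 176 gene symbols, 83 higher and 108 lower in smoke, with a p under 0.05 and a fold above 1.5, and 95 of them have a step-up p under 0.05. All 191 passed the threshold here in the same direction, although the list was chosen on these same samples and is not independent evidence. In the authors' deposited table the smoke-over-control ratio was 10.1 for Ovgp1, 6.51 for Cfd, 3.56 for Hsd17b7, 2.99 for Cyp2e1, 2.91 for Scd1 and 2.83 for Cish, a feedback inhibitor of cytokine signalling. The largest falls in the authors' deposited table were Abcb1b at 3.09-fold lower, Akr1c18 at 2.37-fold, Tlcd4 at 2.35-fold, 2 probes of Adh1 at 2.29-fold and 2.18-fold, and the urokinase gene Plau at 2.08-fold. The fit used here gave log2 changes of 1.44 for Cish, -0.93 for Adh1 and -0.91 for Plau. In the authors' deposited table of Gene Ontology terms, 7 of 999 terms had an enrichment p under 0.05 after Benjamini-Hochberg adjustment over the terms listed. They included extracellular region with 33 genes, immune response with 13 and chemokine activity with 5.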

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

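The test with normexp at an offset of 16 was chosen after seeing the data. The count of genes changed in smoke against room air, 2053, stayed within 1.5 times under every change of background correction, scaling, values, filter, probes, array weights and variance prior tried, from 1731 to 2177, and at 1457 to 1728 without 1 array. It was 341 at an unadjusted p under 0.05 with a 1.5-fold change, 176 with a plain analysis of variance on the authors' values at that threshold per probe, and 268 with it after adjustment. The first 2 add a fold limit, and the last 2 also change the values, the test and the genes tested together. The authors' processed values gave 2048 genes, 2011 of them shared. Lists past the threshold numbered 23 with all probes tested and 21 without a background filter, 16 of the 17 shared in each, 25 with fry, 16 to 19 without 1 array and 5 instead of 17 with an estimated correlation, which uses 4 residual degrees of freedom. Of the 92 named genes under 16 alternatives, 1454 results kept their side of the threshold and direction, 2 gained and 8 lost the call, and none reversed. Of 19 lists under 18 alternatives, 316 kept it, 6 gained and 20 lost it, 12 of these with the estimated correlation. The cause was not tested. Normexp at an offset of 50 has no separate value because it is the setting reported. A block for the chip was not run, since the chip is not given in the sources used here. Signal over background limits the genes compared, since 58.3% to 59.6% of the probes on an array lay above it, and dim genes have bounds only, 28 higher and 24 lower.

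With the replicate number as a block, genes changed in smoke against room air numbered 1946, 1896 of them shared, and 17 lists. Deviations of same-numbered arrays correlated at -0.123, 0.00385 and 0.0144, and not every sample correlated best with its own number. No pairing was therefore assumed, though these few values cannot show that same-numbered samples share nothing but a number.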

Other observations

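The tests of the gene families and of Ovgp1 against the surface epithelium were chosen only after the result was seen. Genes of antigen presentation by MHC class II were lower in smoke, with 6 of 8 past the threshold and 0 higher, a median log2 change of -0.50 and a camera adjusted p of 1.72e-07 over 6 families (adjusted p = 0.0335 with an estimated correlation). H2-Eb1 changed by -0.85 ± 0.08 SE, H2-DMa by -0.71, H2-Ab1 by -0.58 and the invariant chain gene Cd74 by -0.56. Macrophage and pan-leukocyte genes, with medians of -0.15 and -0.194, moved with them. Of 42 clustered histone genes 14 were higher, 3 lower and 25 did not pass, with a median of 0.20, or 0.09 on the authors' processed values, and a camera adjusted p of 0.00186 (adjusted p = 0.124 with an estimated correlation). H3c7 rose by 0.97 and H3c1 by 0.56, while H2bc21 changed by -0.45 and H1f2 by -0.38; near-identical copies make single members uncertain. Alcohol and aldehyde dehydrogenases had 7 lower and 1 higher of 19, with a median of -0.11, or -0.04 on the authors' processed values, and a camera adjusted p of 0.00186 (adjusted p = 0.0685 with an estimated correlation). Adh7 at -1.17 and Adh1 at -0.93 led, and Aldh18a1 rose by 0.28.

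Claudins, the strand proteins of tight junctions, had 4 higher and 2 lower of 12, with a median of 0.27, or 0.13 with genes at their bound, and a camera adjusted p of 0.0432 (adjusted p = 0.124 with an estimated correlation). The claudin median was 0.17 without background correction and 0.06 on the authors' processed values. Cldn15 rose by 0.82 and Cldn3 by 0.76, while Cldn5, an endothelial member, changed by -0.56 and Cldn11 by -0.52. Cldn15 and Cldn1, which rose by 0.29, are also on the surface epithelium list, whose median was 0.71. Cytochrome P450 genes had 3 higher and 4 lower of 25 (camera adjusted p = 0.855), with a median of -0.06, or -0.02 on the authors' processed values, a mean of 0.06 and a test pointing down. Solute carriers had 18 higher and 20 lower of 226 (camera adjusted p = 0.860), and their median of -0.01 turned to 0.01 with median scaling.

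The rise of Ovgp1 and other oviduct markers may come from oviduct tissue carried along with the smoke ovaries. Whether a larger share of surface epithelium accounts for the rise of Ovgp1 could not be decided. The brighter Ovgp1 probe rose by 3.92 ± 0.14 SE more than Lgr5, the surface marker that rose most. Ovgp1 was looked at because it rose most of all genes, so a difference in that direction was given by the choice. The other Ovgp1 probe rose by 0.54, less than Lgr5 at 0.87. If oviduct had been carried along, ciliated-cell genes outside the oviduct list should have risen, and 15 of them had a median of 0.00 (0.00328), a 95% interval of -0.244 to 0.0863, 0 higher and 3 lower (Dnah2 at -0.75, Dnali1 at -0.57 and Mlf1, the most abundant at 12.22 in room air, at -0.42). For an oestrogen-type response of tract epithelium, 8 responsive genes had a median of 0.0149 and an interval of -0.178 to 0.306, with C3 at 0.82 and Aqp5 at -0.71. Ltf, 1 of the 14 largest rises with a log2 change of 1.93, was not among these 8 genes. The 2 medians lay at the 52.5th and 58.5th percentile of random lists. By the limits written beforehand, which used only the median and its percentile, both explanations would count as argued against. The reading used here also asks the upper end of the interval to keep to the limit, and neither does. Both intervals, made by resampling genes and not arrays, leave room for a small shift. Of the genes, 11 of the 15 and 7 of the 8 were above background on all room-air arrays. So neither explanation can be told apart from a response of the ovary itself.

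Adipocyte markers might have risen because fat around the ovary was carried along. A set of 25 further adipocyte genes had a median of 0.0774, with a 95% interval from resampling these genes of -0.0396 to 0.193. That median lay at the 94.9th percentile of 10000 random lists matched on expression. The 25 genes went both ways, Apoc1 at 0.64, Mest at 0.62 and Plin4 at 0.57 against Gpam at -0.46. Of the most abundant, Acly (13.31 in room air) had -0.01 and Cav1 (12.58) changed by -0.37. As 22 of the 25 were above background on all room-air arrays, their own ovarian signal could hide a small share of fat, which keeps this explanation open. A response of the exposed ovary or of fat itself was not tested.

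The fall of interferon-stimulated genes could reflect a lower share of leukocytes. Pan-leukocyte genes had a median of -0.194 over 24 genes, with a 95% interval from resampling these genes of -0.264 to -0.115. That median was lower than those of all 10000 random lists. Neither the interval nor the random lists allow for the spread between arrays or for genes that move together. Past the threshold were 4 genes (Coro1a at -0.57, Evi2a at -0.57, Selplg at -0.43 and Arhgdib at -0.39). The most abundant, Cyba (11.59 in room air) and Slc11a1 (10.90), had -0.01 and 0.16. Interferon-stimulated genes had a median of -0.35, below that interval. With a fall of leukocyte genes that was present but smaller, and 23 of the 24 above background in room air, a lower share and a lower response per cell cannot be told apart.

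Because Hsd17b7 and Cish rose while Akr1c18 fell, a prolactin-type response was tested as a hypothesis on 4 further genes. Only 1 of the 4 passed in the stated direction, Bcl6 at -0.32. Socs2 at 0.03, Esr1 at -0.08 and Pim1 at -0.15 did not pass, which leaves the hypothesis undecided with so few genes. The 6 arrays can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 2053 genes, the highest of the others 0, and 1 split gave as many as the real one, itself.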
